A study of Mus musculus with 12 samples.

How the data were processed

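Liver RNA was measured by RNA sequencing in 12 female mice, 1 library per mouse, with 4 mice in each of 3 groups. Per the labels' protocols, total RNA was extracted with a kit for lipid-rich tissue and libraries were made with a directional kit. All 12 mice were wild type at Khdc3 and differed in the genotype of their grandparents. Per the submitters' processing notes, cutadapt, HISAT2 and DESeq2 were used with the mouse genome build GRCm38; their versions, their roles and the gene counter are not given in the sources used here, nor is whether the counting used strand. Reads of overlapping genes on opposite strands are therefore treated as uncertain, as are reads of near-identical family members such as the Mup, Cyp2c, H2-Q and Or5m genes, the globins and Rps2, which has many processed copies.

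The deposited table holds log2 values by the authors, log2(normalized count + 0.1), for 25069 genes in 12 columns, all of which were used. The normalized count is a read count divided by 1 factor per library, which is read from the values and is not stated in the labels. After 0.1 was taken off the antilog, 100% of the values of each library came out as whole multiples of 1 step to within 0.001 of a read, so that whole reads and library totals could be recovered. After each set was divided by its own mean, the recovered factors lay within 0.29% of median-of-ratios factors computed from those reads. Genes were matched by Ensembl ID to GENCODE M21, which gave coordinates on GRCm38 for 25016 genes; 342 of 395 blank symbols were filled from it and 97.6% of the symbols compared were equal. There were 531 genes with 0 reads in every library.

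Library totals ran from 25070718 to 35843972 reads assigned to genes. The ratio of 2 groups for a gene with 1 to 3 reads in the lower group is given with an exact Clopper-Pearson interval at 95%, and a group with 0 reads is given a floor of 3 reads over the group, from which an at-least fold was computed. Such intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

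The test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with 1 fit of the 3 group means over the 12 libraries, a mean-variance trend, and Benjamini-Hochberg adjustment over the genes of each contrast at 0.05. Genes with a mean of at least 10 over the 12 libraries were tested, 14473 in all. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. Every adjusted p of a gene comes from this test. The contrasts were WTMM against WT, WTPP against WT and WTMM against WTPP, the last being the direct test of a difference between lineages. No covariate was used. The design, the gene lists, the rule for named genes and all but 3 of the alternatives were chosen before the data were examined.

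The 36 gene lists covered pathways of the liver, markers of its cell types and of other tissues, zonation and RNA quality; 35 had at least 3 tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Beside each call stands camera with a correlation estimated from the data, and fry was run as a further alternative. Named genes were, for each contrast against WT, the 10 with the largest positive and the 10 with the largest negative log2 fold change among genes past the threshold with a mean of at least 50 in the higher group, no overlap between libraries of the groups and a symbol that is not a predicted gene, pseudogene, clone or Riken name; for WTMM against WTPP these were 5 and 5. From each list up to 4 members past the threshold with the smallest p were added, or the 3 with the smallest p where a called list had none past it, and Khdc3 always. Other genes were chosen after their values were seen and are named as such.

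The procedure was tested on simulated data drawn from the means and library sizes of the real genes with genes changed by known amounts. The spread of each gene was shrunk toward the trend over the mean, and genes were drawn independently. Effects that many genes of a library share are therefore not covered, and the rates may not hold for the real calls. At true log2 changes of -1 and 1 it recovered 84.0% and 83.7% of changed genes for WTMM against WT, 90.0% and 88.0% for WTPP against WT, and 78.7% and 88.0% for WTMM against WTPP; at -2 and 2 the shares were 95.9% and 98.0%, 97.9% and 100%, and 93.8% and 98.0%. Of the calls, 4.5%, 2.5% and 4.6% were unchanged genes, among 14432, 14433 and 14433 genes tested.

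The 18 pairs of libraries within groups differed by far more than counting noise, with a mean chi-square per gene of 24.4 to 98.4 and Pearson r of 0.975 to 0.990 on the log2 scale across genes, which are not independent replicates; each library was counted once. The WT libraries carry library numbers apart from the others, and the labels give no sequencing or collection batch; if such a batch followed these numbers, the batch and the contrast with WT cannot be told apart. Both comparisons with WT share the same 4 control libraries, so shared calls are set beside simulated unchanged groups and beside splits of the controls.

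Alternatives changed the pseudocount, the filter on low genes, the scaling, the libraries in the fit, the trend, robust and weighted fits, a minimum fold and a block by mouse number, and left out each library in turn. A voom fit of the recovered reads, a fit without WTPP 2 and 3 and a fit with a clock phase score as a covariate were added after the data were seen. Count models were not run. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9.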

Results

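Livers of 12 female mice were profiled by RNA sequencing, with 1 library per mouse. All 12 mice were themselves wild type for Khdc3, a gene of the oocyte's subcortical maternal complex, and the 3 groups of 4 differed in their ancestry. The WT mice had only wild-type ancestors, the WTMM mice descended from Khdc3-null grandmothers on the maternal and the paternal side, and the WTPP mice descended from Khdc3-null grandfathers on both sides. The comparisons ask whether ancestors that lacked the gene leave a trace in the liver transcriptome of descendants wild type for it. They also ask whether the trace depends on the sex of those ancestors. Libraries held 35843972, 29818507, 28028650 and 35755266 reads assigned to genes in WT 116, 117, 118 and 120, then 25070718, 33924490, 25538513 and 28951088 in WTMM 6, 7, 8 and 9, and 28406516, 32612352, 26172914 and 31006168 in WTPP 2, 3, 6 and 7. Between 19272 and 20395 genes had at least 1 read per library, and the 10 highest genes took 17.1% to 21.9% of the normalized counts.

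Khdc3 itself (ENSMUSG00000092622.8, chromosome 9, 73101836 to 73104438, GRCm38) had 7 reads in all 12 libraries together, in WT 116, WTMM 8, WTPP 6 and WTPP 7, with at most 3 in 1 library, so its level in liver was too low to test or to check the labels. Of its partners in the oocyte complex, Ooep had 1 read in all, while Tle6 with 526 reads and Zbed3 with 1213 reads were detected in all 12 libraries. The first principal component of the tested genes, 28.1% of the variance, placed the WT libraries at -52.22 to -19.77 and the 8 descendant libraries at 9.26 to 24.76. The second, 18.9%, placed WTMM at 17.02 to 36.34 and WTPP at -29.49 to -21.43.

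Livers of WTMM mice, the descendants of null grandmothers, had, as lists, higher transcripts of fatty acid oxidation and male-predominant genes than WT livers, and lower transcripts of macrophages, lymphocytes, antigen presentation and the acute phase. With an estimated correlation 0 of the 16 called lists stood. Pck1, the rate-limiting enzyme of gluconeogenesis (chromosome 2, 173153048 to 173159273), rose 2.16-fold (log2 fold change 1.11 ± 0.14 SE, adjusted p = 0.000729). Hsd3b5, a steroid reductase typical of male liver (chromosome 3, 98618634 to 98630252), rose 5.69-fold from 275 ± 97.2 to 1640.0 ± 802 normalized counts (SD, n = 4 per group). Csf1r, the macrophage growth factor receptor (chromosome 18, 61100598 to 61132149), was 2.35-fold lower, at 3331 ± 732 in WT and 1394 ± 70.8 in WTMM. In all, 643 genes rose and 859 fell of 14473 tested. Of these, 141 and 310 changed at least 2-fold.

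Among single genes with the largest rises in WTMM were a pair of neighbouring olfactory receptor genes on chromosome 2. Or5m3b (ENSMUSG00000045392.8, 86020633 to 86045171) went from 1.23 ± 1.34 to 321 ± 139 normalized counts, a 154-fold rise (log2 fold change 7.27 ± 0.55 SE, adjusted p = 1.68e-05). Its neighbour Or5m9 (ENSMUSG00000102091.2, 86045861 to 86050742) had 0 reads in WT and 323 in WTMM, at least 124-fold higher from a floor of 3 reads over the group. Its fitted log2 fold change was 6.33, and 4.08 with a pseudocount of 5. The pair is close in sequence and position, so how their reads divide is uncertain. Capn3, a calpain protease (chromosome 2, 120456019 to 120504913), rose from 2.89 ± 2.29 to 112 ± 58.9. Trhde, the enzyme that degrades thyrotropin-releasing hormone (chromosome 10, 114398823 to 114802307), rose from 24.2 ± 15.5 to 330.5 ± 146. The major urinary proteins, carriers of male pheromones, also rose, with Mup17 at 6.43-fold (log2 fold change 2.69 ± 0.50 SE, adjusted p = 0.00601), Mup14 at 9.43-fold and Mup16 at 5.51-fold. These near-identical genes share reads. Ppp1r3g, a glycogen-targeting subunit, rose 10.2-fold, a call lost without WTMM 6 (adjusted p = 0.0557) and with voom (adjusted p = 0.192). Gadd45g, a stress-response gene, rose 6.03-fold (adjusted p = 0.0152).

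Fatty acid oxidation was the lipid list that was higher in WTMM. Not called were the lists of cholesterol synthesis (0 of 25 rose and 0 fell, median -0.17, camera adjusted p = 0.0936) and fatty acid synthesis (2 of 23 rose and 2 fell, median -0.18, camera adjusted p = 0.527). Lipoproteins were not called either (3 of 25 rose and 0 fell, camera adjusted p = 0.941, with median and mean below 0 and the test above). Of 33 tested genes of fatty acid oxidation and PPARA targets, 15 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 3.53e-11, adjusted p = 0.174 with an estimated correlation). They included Angptl4, a fasting-induced inhibitor of lipoprotein lipase, which rose 2.29-fold (1.20 ± 0.20 SE on the log2 scale, adjusted p = 0.00406), the carnitine carrier Slc25a20 at 1.42-fold, and Cpt1a, which admits fatty acids to mitochondria, at 1.44-fold (adjusted p = 0.0171, and 0.0512 without WT 116). Of 22 genes of the glucose and insulin response, 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.13, camera adjusted p = 0.0439, adjusted p = 0.414 with an estimated correlation). The camera call of that list was lost without WT 116, WT 118, WT 120, WTMM 7, WTMM 8 or WTPP 7 (adjusted p = 0.112, 0.0806, 0.0564, 0.0744, 0.106 and 0.0524), with quantile normalization (0.21), with a mean of at least 50 (0.0712), without the trend (0.0518) and with fry (0.0541). Beside Pck1, the list's glucose-6-phosphatase gene G6pc rose 3.15-fold (adjusted p = 0.0227), a call lost without WT 116, WT 118, WTMM 6, WTMM 7 or WTMM 8 (adjusted p = 0.0683, 0.0674, 0.0557, 0.0516 and 0.058) and with the robust fit (0.0548).

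The bile acid and male-predominant lists were also higher in WTMM, although most bile acid genes did not pass. Of 22 genes of bile acid synthesis and transport, 5 rose and 0 fell (7 and 0 adjusted over the list alone; median log2 fold change 0.25, camera adjusted p = 0.00542, adjusted p = 0.174 with an estimated correlation). The sterol exporters Abcg5 and Abcg8 rose 1.66-fold and 1.75-fold (adjusted p = 0.00343 and 0.00593), and Cyp7b1, an oxysterol hydroxylase, rose 2.37-fold from 2009 ± 331 to 5060.0 ± 2110 normalized counts. Of 18 male-predominant genes, 8 rose and 2 fell (12 and 2 adjusted over the list alone; median 0.76, camera adjusted p = 1.33e-05, adjusted p = 0.174 with an estimated correlation). Mup3 rose 2.57-fold (adjusted p = 0.000817) and Mup7 4.62-fold (adjusted p = 0.00799). Cyp7b1 and the organic anion carrier Slco1a1 belong to both lists. Slco1a1 rose 1.64-fold (adjusted p = 0.0127). Sult2a1, a sulfotransferase typical of female liver, was 3.88-fold lower (log2 fold change -1.96 ± 0.39 SE, adjusted p = 0.00836), and Cyp2b10, the classical target of the receptor CAR, 4.71-fold lower (adjusted p = 0.014), while Nr1i3, which encodes CAR, rose 1.63-fold (adjusted p = 0.00229). As whole lists, the 21 female-predominant genes (4 rose, 2 fell, camera adjusted p = 0.455) and the 33 drug metabolism genes (1 rose, 3 fell, camera adjusted p = 0.527) did not pass.

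Transcripts of leukocytes were lower in WTMM across every leukocyte list tested. Of 12 Kupffer cell markers 11 fell (12 adjusted over the list alone; median -0.93, camera adjusted p = 3.24e-11, adjusted p = 0.174 with an estimated correlation), with Marco 5.90-fold, Adgre1 2.06-fold and C1qa 1.94-fold lower. Of 12 T and NK cell markers 11 fell (12 adjusted over the list alone; median -1.46, camera adjusted p = 6.34e-10, adjusted p = 0.174 with an estimated correlation), among them Cd4, from 108 ± 25.2 to 34.1 ± 7.66 normalized counts, and Nkg7, 3.72-fold lower. Of 9 B cell markers 6 fell (9 adjusted over the list alone; median -1.44, camera adjusted p = 1.28e-06, adjusted p = 0.174 with an estimated correlation), with the immunoglobulin genes Ighm 2.92-fold and Igkc 2.98-fold lower. Of 6 neutrophil markers 5 fell (6 adjusted over the list alone; median -1.82, camera adjusted p = 4.14e-05, adjusted p = 0.174 with an estimated correlation), including S100a8, 4.29-fold lower. Summed over its genes, the Kupffer list held 33150 ± 10370 normalized counts in WT and 16640 ± 1884 in WTMM, and the T and NK list 776 ± 277 and 275 ± 11.8 (SD, n = 4).

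The lists of antigen presentation, interferon response and acute-phase genes were lower along with the leukocyte markers, although most interferon and acute-phase genes did not pass. Of 19 antigen presentation genes 12 fell (16 adjusted over the list alone; median -0.55, camera adjusted p = 2.66e-12, adjusted p = 0.174 with an estimated correlation). The class II genes led, with their transactivator Ciita 4.47-fold lower (log2 fold change -2.16 ± 0.21 SE, adjusted p = 0.000112), H2-Aa 4.24-fold lower (adjusted p = 0.000766) and the invariant chain Cd74 3.53-fold lower (adjusted p = 0.000766). Of 26 interferon response genes 5 fell (8 adjusted over the list alone; median -0.57, camera adjusted p = 2.62e-07, adjusted p = 0.414 with an estimated correlation, fry adjusted p = 0.0743), among them the guanylate-binding protein gene Gbp2, 2.32-fold lower. Of 27 acute-phase genes 8 fell (13 adjusted over the list alone; median -0.42, camera adjusted p = 4.16e-06, adjusted p = 0.323 with an estimated correlation). Orm2 went from 1690.0 ± 1249 to 276 ± 58.3 normalized counts, and the heme carrier Hpx was 1.97-fold lower (adjusted p = 0.00486).

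The lists of pancreatic, erythroid and mesothelial markers were lower too. The 3 adipocyte markers were not called (0 rose and 0 fell, median 0.05, camera adjusted p = 0.949, with the median and mean above 0 and the test below). Of 9 pancreatic acinar markers 7 fell (7 adjusted over the list alone; median -4.92, and -5.23 with the 3 genes at 0 reads set to their bounds; camera adjusted p = 5.16e-08, adjusted p = 0.174 with an estimated correlation). The 3 were Pnlip, Clps and Cel, digestive enzymes and a cofactor of the exocrine pancreas. They were at least 168-fold, 68.4-fold and 68.4-fold lower than in WT, which held 579, 236 and 236 reads. Cpb1, an acinar gene outside the list, also had 0 reads in WTMM and 662 in WT, at least 192-fold lower. Without WT 116 these bounds were 79.8, 31.2, 28.8 and 56.3. Each gene was above 0 in all 4 WT libraries, and Cpb1 was highest in WT 116, at 407 normalized counts against 15.2 to 63.2 in the other WT libraries. A pseudocount of 5 brought the mean of the list from -4.13 to -2.64. Only Cela1 and Cela2a of that list had a mean of at least 10 in every group. Of 7 erythroid markers 1, the heme synthesis gene Alas2, fell (4 adjusted over the list alone; median -1.93, camera adjusted p = 0.00429, adjusted p = 0.414 with an estimated correlation, fry adjusted p = 0.0872). The Alas2 call was lost in 11 of the alternatives, with adjusted p from 0.0523 to 0.118 there, including without WT 116, WT 117, WT 120, WTMM 6, WTMM 7, WTMM 9 or WTPP 3 (0.118, 0.0579, 0.0878, 0.106, 0.0904, 0.111 and 0.0525). Of 6 mesothelial and gallbladder markers 2 fell (4 adjusted over the list alone; mean -0.97, camera adjusted p = 0.000178, adjusted p = 0.174 with an estimated correlation). Those 2, the keratin genes Krt18 and Krt8, are also made by hepatocytes and had log2 fold changes of -0.89 and -0.59 (adjusted p = 0.000422 and 0.00486).

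**Figure D1:**
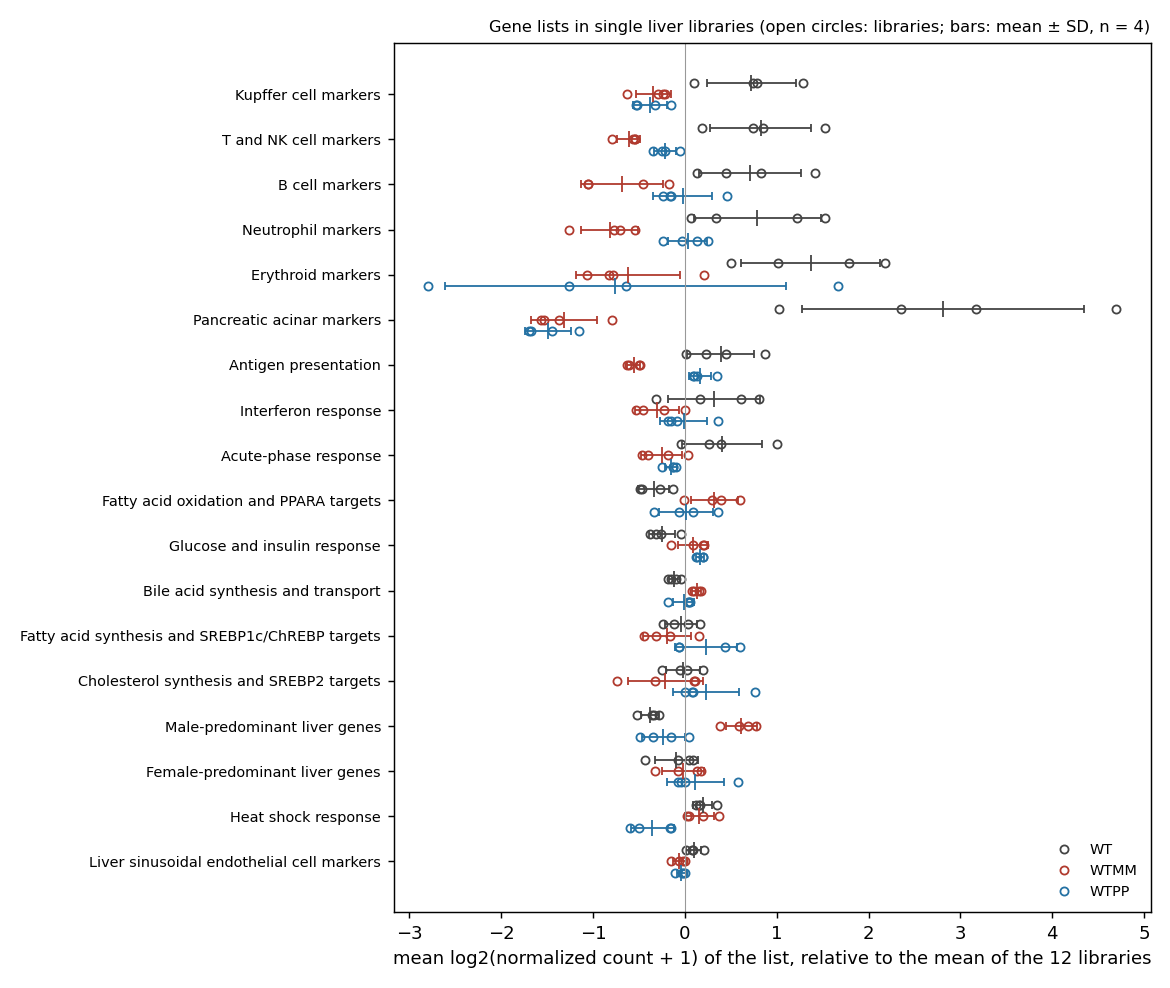
Mean log2(normalized count + 1) of each gene list in each liver library, relative to the mean over the 12 libraries (x axis), for the lists on the y axis; open circles are libraries and bars the mean ± SD (n = 4 per group). The Kupffer list averaged 0.725 in WT, -0.343 in WTMM and -0.382 in WTPP, and WT 116 lay highest in WT at 1.28.

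Smaller shifts were called for lists in which no gene passed on its own. Of 12 sinusoidal endothelial markers 0 rose and 0 fell (0 and 0 adjusted over the list alone; median -0.20, camera adjusted p = 0.0146, adjusted p = 0.255 with an estimated correlation). The vessel receptor gene Kdr had a log2 fold change of -0.22 ± 0.08 SE (adjusted p = 0.0936). That call was lost without WT 118 (adjusted p = 0.0638) or WTMM 7 (0.0509). Of 28 cytosolic ribosomal protein genes 0 rose and 0 fell (0 and 0 adjusted over the list alone; median -0.13, mean -0.11, camera adjusted p = 0.0382, adjusted p = 0.933 with an estimated correlation, fry adjusted p = 0.511). The ribosomal call was lost without WT 116 (adjusted p = 0.493, mean -0.04), WTMM 8 (0.116) or WTMM 9 (0.0594) and without the trend (0.0518).

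At an unadjusted p under 0.05 there were 3954 genes in this comparison. The number of called genes fell from 1502 to 838 without WT 116, 842 without WT 118, 913 without WTMM 6, 822 without WTMM 7 and 893 without WTMM 9, and rose to 2655 with array weights. Groups did not overlap for 1337 of the called genes and for 18.8% of all tested genes, where chance gives 2.86%.

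Livers of WTPP mice, the descendants of null grandfathers, had, as lists, lower transcripts of Kupffer cells, lymphocytes, the acute phase and heat shock proteins than WT livers, and higher transcripts of fatty acid oxidation genes. With an estimated correlation 0 of the 15 called lists stood, and fry called 4 lists, without those of B cells, the acute phase and fatty acid oxidation. Cyp17a1, a steroid hydroxylase and lyase (ENSMUSG00000003555.7, chromosome 19, 46667165 to 46673172), rose 15.2-fold from 285 ± 153 to 3921 ± 748 normalized counts (SD, n = 4 per group; log2 fold change 3.92 ± 0.36 SE, adjusted p = 0.000124). Igfbp1, an insulin-repressed binding protein of insulin-like growth factors (chromosome 11, 7197782 to 7202546), rose 16.0-fold from 110 ± 36.9 to 1773 ± 594. Hspa8, the constitutive heat shock chaperone (chromosome 9, 40800984 to 40810087), was 1.85-fold lower (log2 fold change -0.89 ± 0.15 SE, adjusted p = 0.00335). In all, 678 genes rose and 801 fell, and 144 and 224 of these changed at least 2-fold.

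Other large rises in WTPP were Defb1, an epithelial defensin (chromosome 8, 21776599 to 21795185), from 3.84 ± 4.40 to 70.7 ± 27.7 normalized counts, Cdcp1 at 7.55-fold and Trmt9b at 6.83-fold. H2-Eb1, a class II beta chain (ENSMUSG00000060586.10, chromosome 17, 34305867 to 34316674), rose 6.51-fold from 112 ± 60.0 to 680.2 ± 139 (log2 fold change 2.70 ± 0.30 SE, adjusted p = 0.000358) while the class II gene H2-Aa and the invariant chain Cd74 fell. The early response genes Nr4a1 and Dusp1 rose 5.34-fold and 4.64-fold (adjusted p = 0.000276 and 0.000925). Their list of 18 immediate early genes was not called, with 4 higher and 0 lower in WTPP (camera adjusted p = 0.0961) and 3 higher and 2 lower in WTMM (0.915, with the median below 0 and the mean above). Rps2 on chromosome 17, 24718116 to 24721929, rose 5.13-fold (adjusted p = 0.000124), a ribosomal gene whose many processed copies make its count uncertain. Cyp2c39 on chromosome 19, 39510862 to 39568529, one of a cluster of similar Cyp2c genes, was 31.4-fold lower (adjusted p = 0.00756), with 17526 normalized counts in WTPP 6 and 259 to 381 in the other WTPP libraries against 26660 ± 2462 in WT. Lcn2, an iron-scavenging acute-phase protein, was 8.46-fold lower (adjusted p = 0.00589).

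**Figure D2:**
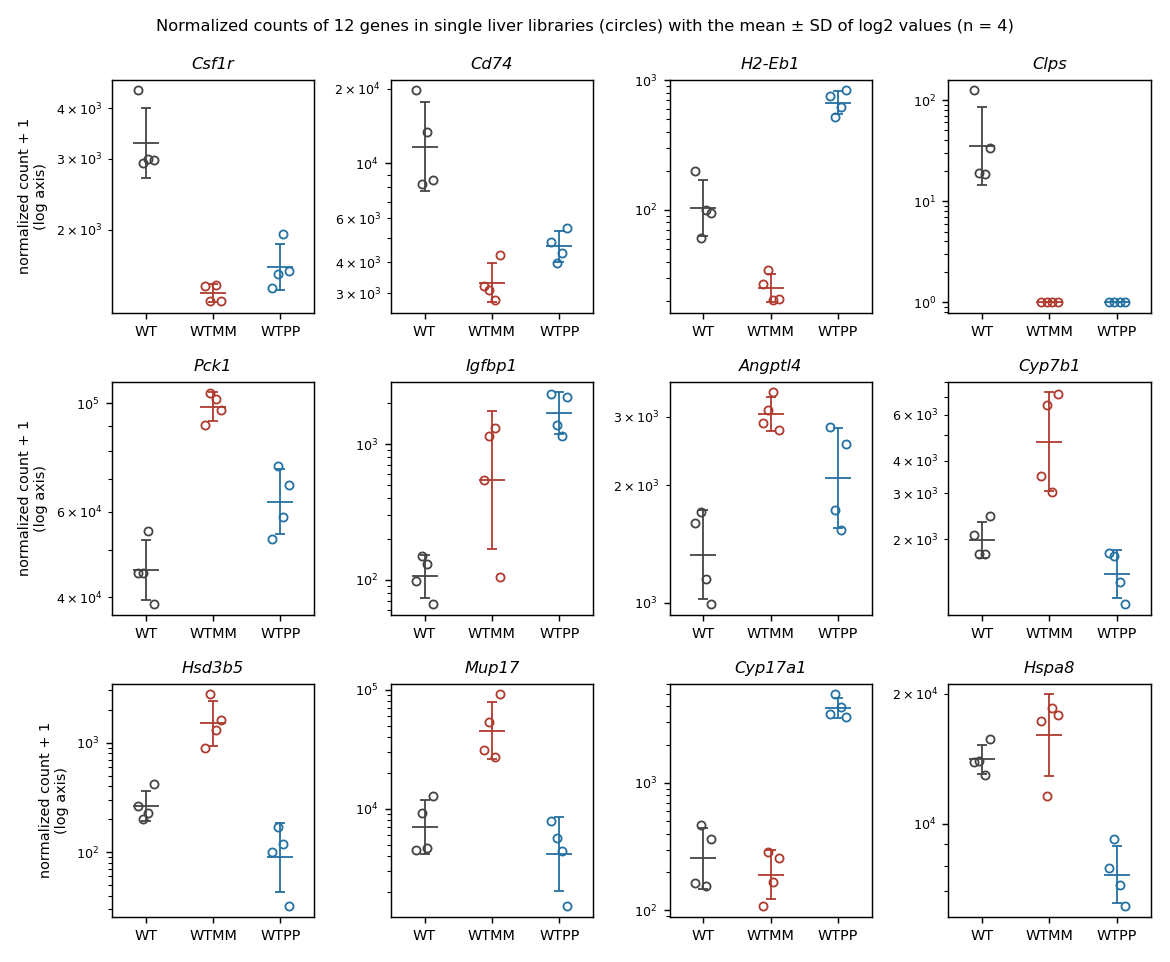
Normalized counts plus 1 (log y axis) of 12 genes in each liver library, by group (x axis); circles are libraries and bars the mean ± SD of the log2 values (n = 4 per group). Cyp17a1 and H2-Eb1 averaged 3921 and 680.2 in WTPP against 203 and 24.6 in WTMM, while Hsd3b5 averaged 1640.0 in WTMM and 104 in WTPP.

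Of the metabolic lists, fatty acid oxidation and PPARA targets had 5 of 33 genes higher and 0 lower (7 and 0 adjusted over the list alone; median log2 fold change 0.29, camera adjusted p = 3.19e-05, adjusted p = 0.621 with an estimated correlation, fry adjusted p = 0.124). Ehhadh, a peroxisomal oxidation enzyme, rose 1.78-fold (adjusted p = 0.0106, and 0.0584 with WTPP 2 and 3 left out). In the glucose and insulin response 3 of 22 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.21, camera adjusted p = 0.0127, adjusted p = 0.621 with an estimated correlation, fry adjusted p = 0.0622). Igfbp1 kept its call under every alternative, while those of G6pc and Pck1 (adjusted p = 0.0427 and 0.0498) were lost in 14 and 18 of 27. G6pc was lost without WT 116, WT 118, WT 120, WTMM 6, WTMM 7, WTMM 8, WTPP 2, WTPP 3 or WTPP 7 (adjusted p = 0.123, 0.122, 0.0576, 0.0548, 0.0562, 0.0505, 0.0979, 0.0879 and 0.0776) and without WTPP 2 and 3 together (0.238). Pck1 was lost without WT 116, WT 117, WT 120, any WTMM library, WTPP 3, WTPP 6 or WTPP 7 (adjusted p = 0.109, 0.057, 0.117, 0.0612 to 0.0657, 0.119, 0.0751 and 0.121) and without the filter (0.127). In fatty acid synthesis 4 of 23 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.0262, adjusted p = 0.656 with an estimated correlation). Malic enzyme Me1 rose 1.91-fold (adjusted p = 0.00289), the carbohydrate-sensing factor Mlxipl 1.49-fold (adjusted p = 0.0115), while G6pdx was 1.61-fold lower (adjusted p = 0.0119, and 0.0672 with WTPP 2 and 3 left out). In cholesterol synthesis 1 of 25, Sc5d, rose (1 adjusted over the list alone; median 0.24, camera adjusted p = 0.0262, adjusted p = 0.774 with an estimated correlation), and the Sc5d call was lost without WT 116 (adjusted p = 0.0531). The synthesis lists were also not called with fry (adjusted p = 0.312 for fatty acids and 0.501 for cholesterol) or quantile normalization (0.0723 for both). Leaving out WT 116, WT 118, WTPP 6 or WTPP 7 ended the call of fatty acid synthesis (adjusted p = 0.13, 0.056, 0.143 and 0.102), and leaving out WT 116, WT 120 or WTPP 6 that of cholesterol synthesis (0.158, 0.0616 and 0.394). Without WTPP 2 and 3 both calls stood and the mean log2 fold changes were larger, at 0.56 against 0.27 and 0.40 against 0.25.

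The heat shock list was lower in WTPP. Relative to the mean of the 12 libraries it stood at -0.503 and -0.602 in WTPP 6 and 7. In WTPP 2 and 3 it stood at -0.164 and -0.148, and in WT at 0.118 to 0.349. Of 15 heat shock response genes 7 fell (10 adjusted over the list alone; median -0.43, camera adjusted p = 9.39e-07, adjusted p = 0.357 with an estimated correlation). Beside Hspa8, Hsph1 was 2.31-fold lower at 1309 ± 555 against 2820.0 ± 101 normalized counts, and the co-chaperones Chordc1 and Stip1 were 1.65-fold and 1.69-fold lower (adjusted p = 0.00228 and 0.0107). Of 19 unfolded protein response genes 1 rose and 0 fell (2 and 6 adjusted over the list alone; median -0.27, camera adjusted p = 0.0267, adjusted p = 0.656 with an estimated correlation, fry adjusted p = 0.227), a call lost without WT 118, WT 120, WTPP 6 or WTPP 7 (adjusted p = 0.1, 0.0672, 0.125 and 0.122). Without WTPP 2 and 3 the mean log2 fold change of that list was -0.57 against -0.27. Of 28 cytosolic ribosomal protein genes 1, Rps2, rose and 2 fell (2 and 8 adjusted over the list alone; median -0.23, mean -0.11, camera adjusted p = 0.000578, adjusted p = 0.656 with an estimated correlation, fry adjusted p = 0.227). Its mean was -0.04 without WT 116, -0.07 without WTPP 2, -0.04 without WTPP 6 and -0.17 without WTPP 7.

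Of the leukocyte lists, those of Kupffer, T and NK and B cells were lower in WTPP. That of neutrophils was not called (0 of 6 rose and 0 fell, 0 and 2 adjusted over the list alone, median -0.88, camera adjusted p = 0.0961). All 12 Kupffer cell markers fell (12 adjusted over the list alone; median -0.94, camera adjusted p = 2.62e-11, adjusted p = 0.357 with an estimated correlation), with Marco 8.32-fold, Csf1r 2.02-fold and Cd68 1.75-fold lower. Of 12 T and NK cell markers 5 fell (11 adjusted over the list alone; mean -1.04, camera adjusted p = 1.52e-06, adjusted p = 0.357 with an estimated correlation), with Cd4 3.20-fold lower (adjusted p = 0.000694). Of 9 B cell markers 3 fell (3 adjusted over the list alone; median -0.66, camera adjusted p = 0.0057, adjusted p = 0.621 with an estimated correlation, fry adjusted p = 0.124), among them Ighm, 1.96-fold lower (adjusted p = 0.0118). With WTPP 2 and 3 left out, neither the list (adjusted p = 0.0635) nor Ighm (0.0662) was called. Of 27 acute-phase genes 2 rose and 9 fell (3 and 15 adjusted over the list alone; median -0.46, camera adjusted p = 6.8e-05, adjusted p = 0.621 with an estimated correlation, fry adjusted p = 0.0917), with Hpx 2.09-fold and Apcs 2.21-fold lower (adjusted p = 0.00306 and 0.00421). Without WT 116 the mean of the acute-phase list was -0.36 in place of -0.56.

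Antigen presentation had 2 of 19 genes higher and 8 lower (2 and 9 adjusted over the list alone; median -0.30, camera adjusted p = 0.0124, adjusted p = 0.656 with an estimated correlation, fry adjusted p = 0.14). Ciita was 3.07-fold, H2-Aa 2.83-fold and Cd74 2.52-fold lower (adjusted p = 0.000694, 0.00468 and 0.00445), opposite to H2-Eb1. The call of this list was lost without WT 116 (adjusted p = 0.0542, mean log2 fold change -0.06 against -0.22) and with WTPP 2 and 3 left out (adjusted p = 0.14), and its mean was -0.35 without WT 117. In the interferon response 1 of 26 genes fell (0 adjusted over the list alone; median -0.18, camera adjusted p = 0.0141, adjusted p = 0.764 with an estimated correlation, fry adjusted p = 0.399). Without WT 116, WT 120 or WTPP 7 (adjusted p = 0.173, 0.139 and 0.0638) and without WTPP 2 and 3 (0.163) it was not called, and without WT 117 its mean was -0.54 against -0.33.

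The pancreatic acinar markers were low in WTPP too, with 7 of 9 lower than in WT (9 adjusted over the list alone; median -5.13, and -5.23 with the 3 genes at 0 reads set to their bounds; camera adjusted p = 1.72e-09, adjusted p = 0.357 with an estimated correlation). Clps and Ctrb1 had 0 reads in WTPP and were at least 71.4-fold and 218-fold lower than in WT, bounds that were 32.6 and 112 without WT 116. Pnlip had 1 read, a ratio of 526 (counting interval 93.9 to 20800), which was 250.0 without WT 116 and at least 128 without WTPP 7. Its call was lost with voom (adjusted p = 0.0526). A pseudocount of 5 brought the mean of the list from -4.30 to -2.77. Of 7 erythroid markers none passed (0 rose and 0 fell; 0 and 5 adjusted over the list alone; median -2.35, camera adjusted p = 0.00477, adjusted p = 0.621 with an estimated correlation, fry adjusted p = 0.124). Hemoglobin beta Hbb-bs, whose reads are shared with its close relatives, held 12320 ± 4880 normalized counts in WT and 4344 ± 5148 in WTPP (adjusted p = 0.0578). Without WTPP 2 and 3 the erythroid mean was -3.40 against -2.13.

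The WTPP livers also differed among themselves in circadian clock genes, which were chosen after their values were seen. Arntl, a core activator of the clock, stood at 933 and 541 normalized counts in WTPP 2 and 3, at 38.8 and 32.0 in WTPP 6 and 7, and at 52.2 to 175 in the 8 other libraries. Dbp is an output gene of the opposite phase. It stood at 140 and 1316 in WTPP 2 and 3, and at 4930.4 and 6545 in WTPP 6 and 7. Its range was 2074 to 3400 in WT and 3667.5 to 4649 in WTMM, without overlap. As a list, 1 of 21 clock genes rose in WTPP (camera adjusted p = 0.69, with the median and mean below 0 and the test above). That gene, Per1, rose 2.43-fold (adjusted p = 0.0375). Its call was lost without WT 116, WT 117, WT 118, WT 120, WTMM 7, WTPP 3, WTPP 6 or WTPP 7 (adjusted p = 0.0969, 0.0532, 0.0783, 0.0636, 0.0504, 0.0655, 0.1 and 0.0964) and in 3 other fits (0.0666 to 0.0842). Without WTPP 2 and 3 its log2 fold change was 1.98 against 1.28. In WTMM Per1 rose 3.58-fold (adjusted p = 0.00741).

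**Figure D3:**
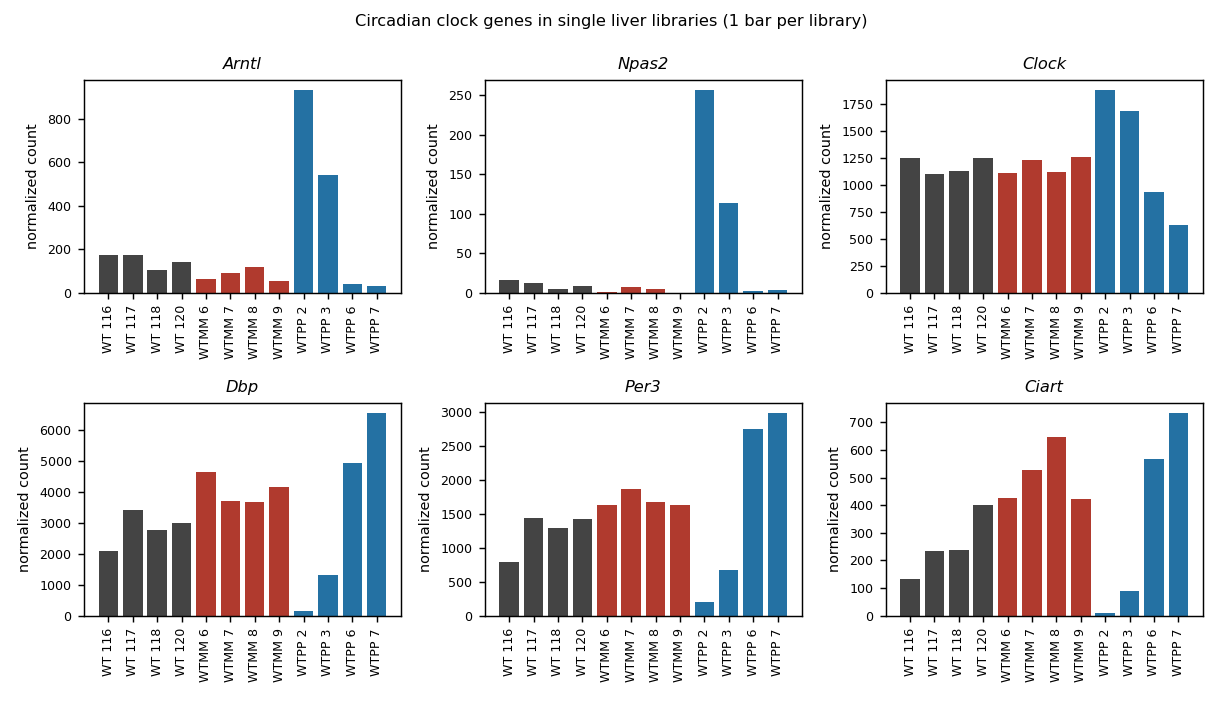
Normalized counts (y axis, from 0) of 6 circadian clock genes in each of the 12 liver libraries (x axis), 1 bar per library, coloured by group. WTPP 2 and 3 stood apart from WTPP 6 and 7, for example at 257 and 113 against 2.2 and 3.7 for Npas2.

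At an unadjusted p under 0.05 there were 3852 genes in the WTPP comparison. The number of called genes was 1479, and 742 without WT 116, 809 without WT 118, 965 without WTPP 6, 855 without WTPP 7 and 858 with only these 2 groups in the fit. Groups did not overlap for 1278 of the called genes and for 15.1% of all tested genes, where chance gives 2.86%.

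Both groups of descendants shared many of their differences from WT. There were 242 genes higher and 382 lower in both comparisons, and 5 with opposite directions, where independent lists of these sizes would share 30.1 and 47.5. Among those lower in both were Csf1r, Marco, Cd4, Ciita, Cd74, Hpx and Krt18, and among those higher in both Dusp1, Abcg8, Nr1i3 and Gadd45g, the last without a call in WTPP when WTPP 2 and 3 were left out (adjusted p = 0.0594). The comparisons share their WT libraries: simulated groups without any effect shared 0.01 higher and 0 lower genes on average over 100 simulations. Genes were drawn independently with equal means there, so hardly any could be called at all. With the WT libraries split 2 and 2, so that no control served both comparisons, 97 to 175 genes were shared over the 6 ordered splits. Independent lists of the sizes found there, 268 to 1075 and 211 to 1195 genes, would share 3.01 to 8.46 higher and 4.28 to 12.8 lower genes. Across genes, which are not independent replicates, the fold changes correlated at Pearson r 0.621 and Spearman rho 0.588, beside 0.501 and 0.461 in the simulation, and their covariance was 0.145 beside 0.0262, a difference of 0.119. Part of the excess may come from the shared controls. With the WT libraries split, Pearson r was 0.412 to 0.493 and Spearman rho 0.319 to 0.420. The covariance was 0.1095 to 0.125 there, so most of it stayed without a shared control library. Neither the simulation nor the splits can remove a property common to all WT libraries. The shared count of 624 was 307 without WT 116, 946 without WT 117, 341 without WT 118, 392 without WTMM 7 and 1065 with array weights.

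Between the lineages, WTMM livers had, as lists, higher male-predominant and heat shock transcripts than WTPP livers, and lower transcripts of fatty acid synthesis and antigen presentation. With an estimated correlation 0 of the 15 called lists stood. In fatty acid synthesis and antigen presentation 5 of 23 and 5 of 19 genes passed the threshold. Hsd3b5 was 16.9-fold higher in WTMM (log2 fold change 4.07 ± 0.44 SE, adjusted p = 0.000329; n = 4 per group), and Cyp17a1 20.3-fold lower (log2 fold change -4.35 ± 0.36 SE, adjusted p = 2.04e-05). H2-Eb1 was 26.9-fold lower in WTMM, at 24.6 ± 6.61 against 680.2 ± 139 normalized counts (SD). Of 14473 genes, 331 were higher and 272 lower in WTMM, of which 94 and 105 differed at least 2-fold.

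Genes that set the lineages furthest apart were often at one extreme in a single lineage. Or5m9 had 323 reads in WTMM and 0 in WTPP, at least 112-fold higher, and Or5m3b had 1257 reads in WTMM and 3 in WTPP, a ratio of 437 (counting interval 149 to 2120.0). Trhde was 14.6-fold higher in WTMM (adjusted p = 0.00418). Sytl5 on the X chromosome, 9885622 to 9994543, was 17.4-fold lower in WTMM (adjusted p = 0.00201), Cyp2c55 15.2-fold lower (adjusted p = 0.00148), and Rps2 6.58-fold lower (adjusted p = 1.98e-05). The nuclear receptor gene Nr4a1 was 4.41-fold lower (adjusted p = 0.000716).

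Of 18 male-predominant genes 6 were higher and 0 lower in WTMM (8 and 0 adjusted over the list alone; median log2 fold change 0.56, camera adjusted p = 1.1e-05, adjusted p = 0.171 with an estimated correlation). Cyp7b1 was 3.21-fold and Mup7 5.61-fold higher (adjusted p = 0.00282 and 0.00727). Sult2a1 and Cyp2b10 were 4.64-fold and 5.66-fold lower in WTMM (adjusted p = 0.00735 and 0.0145; Cyp2b10 at 0.0737 with WTPP 2 and 3 left out), though the lists of female-predominant (2 higher, 4 lower of 21, camera adjusted p = 0.878) and drug metabolism genes (3 higher, 7 lower of 33, camera adjusted p = 0.0593) did not pass. Of 15 heat shock genes 6 were higher (7 adjusted over the list alone; median 0.52, camera adjusted p = 8.43e-07, adjusted p = 0.378 with an estimated correlation), Hspa8 by 2.10-fold and Dnajb1 by 1.68-fold (adjusted p = 0.00148 and 0.00869; Dnajb1 at 0.0503 with WTPP 2 and 3 left out).

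Of 25 cholesterol synthesis genes 1 was lower in WTMM (10 adjusted over the list alone; median -0.40, camera adjusted p = 4.1e-06, adjusted p = 0.572 with an estimated correlation, fry adjusted p = 0.254), and the mean of the list was -0.27 without WTMM 6 and -0.27 without WTPP 6 against -0.45. Of 23 fatty acid synthesis genes 5 were lower (8 adjusted over the list alone; median -0.42, camera adjusted p = 0.00055, adjusted p = 0.549 with an estimated correlation, fry adjusted p = 0.194), and the mean was -0.71 against -0.42 without WTPP 2 and 3. Acss2, which makes acetyl-CoA from acetate, was 2.29-fold lower (adjusted p = 0.0177, with 0.0526 without WTMM 6 and 0.0617 without WTMM 9). Of 33 fatty acid oxidation genes none passed on its own, while the list did (median 0.27, camera adjusted p = 0.00334, adjusted p = 0.757 with an estimated correlation, fry adjusted p = 0.346), a call lost without WTPP 3 (adjusted p = 0.0502). Cpt1a was 1.31-fold higher (adjusted p = 0.101) and Ehhadh 1.43-fold lower (adjusted p = 0.12).

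Immune transcripts were lower in WTMM than in WTPP for several lists. Of 19 antigen presentation genes 5 were lower (9 adjusted over the list alone; median -0.49, camera adjusted p = 3.39e-06, adjusted p = 0.523 with an estimated correlation), including the class I genes H2-K1 at 1.61-fold, H2-Q6 at 2.43-fold and H2-Q7 at 2.84-fold (adjusted p = 0.0118, 0.00259 and 0.00718), of which the H2-Q genes share reads. Of 26 interferon response genes 1 was lower (1 adjusted over the list alone; median -0.30, camera adjusted p = 0.00334, adjusted p = 0.757 with an estimated correlation, fry adjusted p = 0.482), a call lost without WTPP 6 (adjusted p = 0.0764). No B cell marker passed on its own, with Ighm at 87.8 ± 14.9 and 132 ± 29.1 normalized counts (adjusted p = 0.145), while the list of 9 did (median -0.62, camera adjusted p = 0.00433, adjusted p = 0.572 with an estimated correlation, fry adjusted p = 0.254). The Kupffer (camera adjusted p = 0.949), pancreatic acinar (0.637) and erythroid (0.949) lists did not pass between the lineages. A p above the threshold does not show that the groups were equal.

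Several small lists were also lower in WTMM than in WTPP. Of 6 neutrophil markers 1, the gelatinase gene Mmp9, was lower, by 2.24-fold (1 adjusted over the list alone; median -0.76, camera adjusted p = 0.00367, adjusted p = 0.48 with an estimated correlation). With a mean of at least 50 the neutrophil call was lost (adjusted p = 0.144). Of 5 cholangiocyte markers 1 was lower, the biliary transcription factor Sox9, by 2.19-fold (3 adjusted over the list alone; median -0.93, camera adjusted p = 0.00367, adjusted p = 0.356 with an estimated correlation). The Sox9 call (adjusted p = 0.0376) was lost without WT 120, WTMM 7, WTMM 8, WTMM 9, WTPP 2, WTPP 3 or WTPP 6 (adjusted p = 0.0539, 0.0945, 0.0767, 0.113, 0.0937, 0.0807 and 0.0773), and in other fits with adjusted p up to 0.193. Without the filter the cholangiocyte mean was -0.66 against -0.99, and without WTPP 2 and 3 the list was not called (adjusted p = 0.061). Of 6 mesothelial and gallbladder markers 1 was lower (2 adjusted over the list alone; median -0.73, camera adjusted p = 0.00334, adjusted p = 0.48 with an estimated correlation, fry adjusted p = 0.0913), a call lost without WTPP 2 and 3 (adjusted p = 0.0918, mean -0.42 against -0.70). Of 18 immediate early genes 1, Nr4a1, was lower (1 adjusted over the list alone; median -0.30, camera adjusted p = 0.0127, adjusted p = 0.549 with an estimated correlation, fry adjusted p = 0.171). The immediate early call was lost without WTPP 6 (adjusted p = 0.0517) or WTPP 7 (0.073), and its mean was -0.58 against -0.39 without WTPP 2 and 3.

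In the remaining called lists no gene passed on its own. The 13 stellate cell and fibroblast markers were lower in WTMM (0 and 0 adjusted over the list alone; median -0.29, camera adjusted p = 0.00367, adjusted p = 0.48 with an estimated correlation, fry adjusted p = 0.0913), as were the 12 T and NK cell markers (0 and 0 adjusted over the list alone; median -0.44, camera adjusted p = 0.0391, adjusted p = 0.757 with an estimated correlation, fry adjusted p = 0.346). The collagen gene Col1a2 stood at 296 ± 36.0 and 357 ± 37.9 normalized counts in WTMM and WTPP (adjusted p = 0.201). The T and NK call was lost without WTMM 7, WTPP 6 or WTPP 7 (adjusted p = 0.0814, 0.0578 and 0.113), with a pseudocount of 5 (0.0546), a mean of at least 50 (0.607), quantile normalization (0.0913) and voom (0.0625). The 19 proliferation genes were higher in WTMM (0 and 0 adjusted over the list alone; median 0.74, camera adjusted p = 0.0105, adjusted p = 0.757 with an estimated correlation, fry adjusted p = 0.482), with the mitotic kinase gene Cdk1 at 71.0 ± 18.6 against 47.2 ± 41.2 normalized counts (adjusted p = 0.36). The proliferation call was lost without WTMM 8, WTPP 2, WTPP 3 or WTPP 7 (adjusted p = 0.146, 0.0531, 0.0596 and 0.152), without WTPP 2 and 3 (0.468), with a mean of at least 50 (0.253) and with the clock covariate (0.0941). Without WTPP 6 its mean was 1.20 against 0.69.

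**Figure D4:**
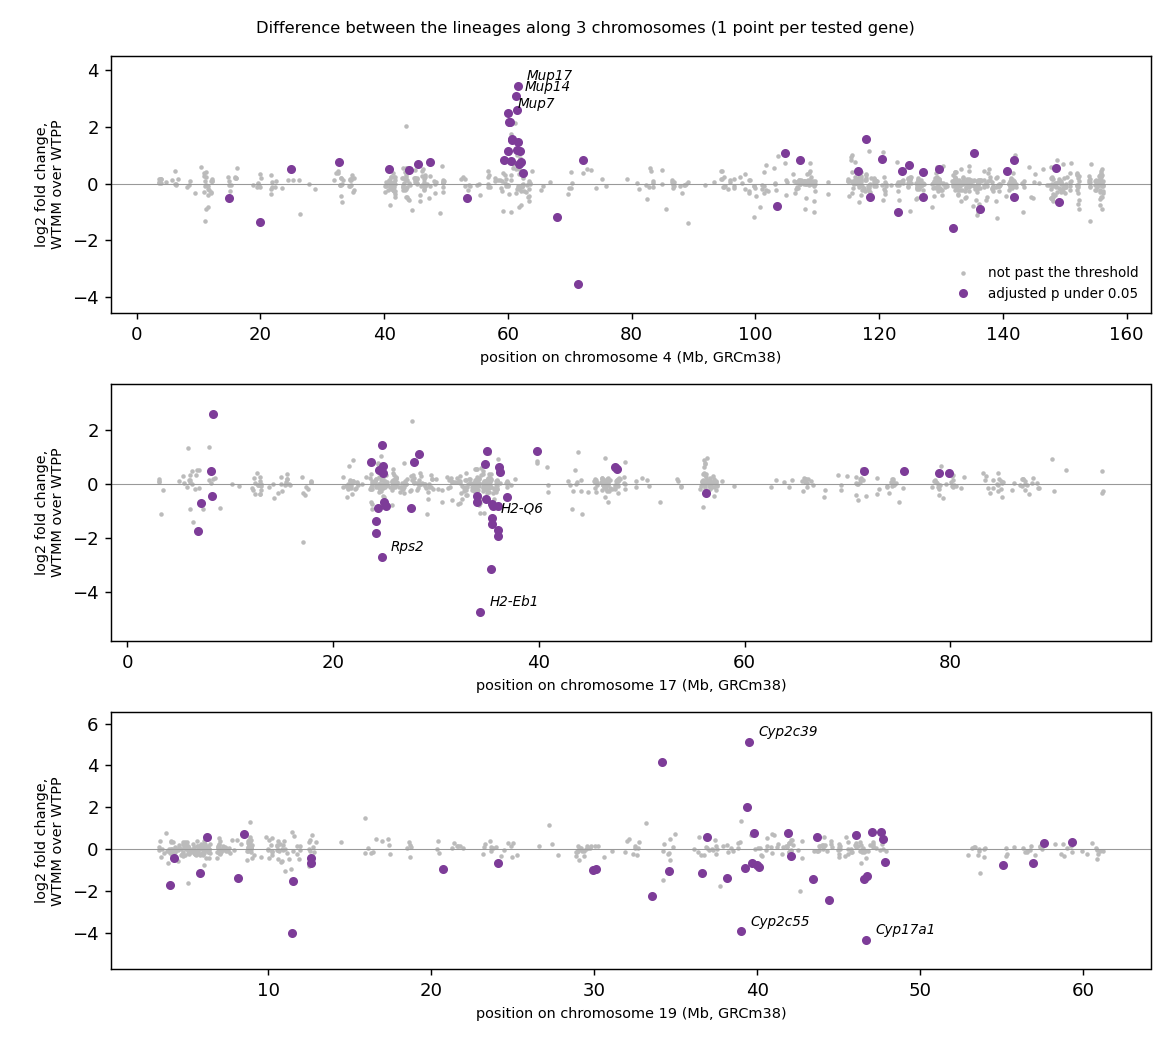
Log2 fold change of WTMM over WTPP (y axis) by gene start on chromosomes 4, 17 and 19 (x axis, Mb on GRCm38), 1 point per tested gene; purple points passed an adjusted p of 0.05. Called genes sat close together near the Mup cluster on chromosome 4, where 12 of 33 tested genes were called in the 2 Mb from 60 Mb, and near the Cyp2c cluster on chromosome 19, where 8 of 18 were called in the 2 Mb from 38 Mb.

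At an unadjusted p under 0.05 there were 2687 genes between the lineages. The number of called genes was 603, and 358 without WTMM 6, 355 without WTMM 7, 397 without WTMM 8, 266 without WTMM 9 and 343 without WTPP 3. Groups did not overlap for 579 of the called genes and for 13.2% of all tested genes, where chance gives 2.86%.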

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

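For the patterns weighed here, the tests of pancreatic tissue, of blood and of clock phase at collection were chosen after the result was seen, and the other tests before. A library was set apart when its gap to the nearest library of its group, as a ratio to the group's range, exceeded the 95% critical value of Dixon's test for 4 values. Of 420 groups of 4 values tested, from the genes kept for the text, the lists and the library totals, 32 met this. Chance gives about 1 in 20.

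In WT 116, pancreatic transcripts stood above the other WT libraries: Cpb1 at 407 normalized counts against 15.2 to 63.2 (ratio 0.878), Clps at 124 against 17.8 to 32.8 (0.858), Reg1 at 276 against 3.03 to 26.5 (0.914) and Try5 at 186 against 9.09 to 31.2 (0.875). The same library was highest for Csf1r, 4428 against 2923 to 2989 (0.956), and G6pdx, 336 against 223 to 231 (0.93). WT 117 was highest for Nr1i3, 6393 against 4994 to 5124 (0.907), and WT 118 for Col1a2 (0.84) and the stellate cell list (0.879). Between 1 and 4 reads in an otherwise empty group gave a ratio of 1.0 for Pnlip in WTPP 7, Ctrb1, Cpa1 and Try5 in WTMM 6, Cpa1 and Cel in WTPP 6 and Or5m3b in WTPP 2.

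WTPP 6 was highest in its group for Cyp2c39, 17526 against 259 to 381 (0.993), Cdk1, 109 against 20.1 to 30.9 (0.878), cholesterol synthesis (0.884), female-predominant genes (0.886) and the interferon response (0.831). WTPP 7 was lowest for bile acid genes (0.893) and lipoproteins (0.906), and highest for antigen presentation (0.855) and B cell markers (0.872). WTPP 3 was lowest for Gbp2 (0.909) and highest for Hpx (0.853). Among the WTMM libraries, number 6 was highest for H2-Q6 (0.94) and nuclear oxidative phosphorylation genes (0.833), number 7 lowest for T and NK markers (0.919), number 8 highest for Sc5d (0.846) and number 9 highest for Dnajb1 (0.899).

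The descendant groups also differed from each other: the direct test of their difference called 603 genes. Only 1 of the 35 ways to split the 8 libraries into equal groups, the real one, gave so many, and the highest other split gave 4. Every other split mixes the real groups, so any difference carried by whole groups would give this. The splits therefore cannot exclude a chance difference shared by the mice of a group, such as a batch. The real grouping also stood alone, with the same limit, for WTMM against WT (1 of 35, highest other 0) and WTPP against WT (1 of 35, highest other 3). So it did for genes called in both (1 of 100 assignments, highest other 1). For the number of called lists chance cannot be excluded, since 8, 8 and 3 of 35 splits called as many in WTMM against WT, WTPP against WT and WTMM against WTPP, with up to 20, 23 and 19 lists in another split and 16, 15 and 15 in the real one.

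At the preset correlation the Kupffer, T and NK, B cell, erythroid and acinar lists were called lower in both descendant groups, and the neutrophil list only in WTMM (camera adjusted p = 0.0961 in WTPP). None of these calls stood with an estimated correlation (adjusted p = 0.174 to 0.621), fry ended the erythroid calls (adjusted p = 0.0872 and 0.124) and the B cell call in WTPP (0.124), and in WTPP no erythroid gene passed, with WTPP 2 at 1.67 above the WT mean of 1.37. Pancreas attached to WT livers is unlikely to have brought the whole leukocyte excess alone, since the summed acinar excess was 2.16% of it, under a bound of 10%. That leukocyte sum includes class II genes and the Kupffer list, at 33150 normalized counts in WT against 16640 in WTMM and 16280 in WTPP. The B cell, T and NK and neutrophil lists summed to only 963, 776 and 434 in WT, beside an acinar excess of 724.5. For these lists the test cannot decide, because the larger Kupffer counts dominate the sum. Residual blood alone is also unlikely to have made the whole pattern, because markers of the liver's resident Kupffer cells moved too, with the smaller of the medians at -0.9277. That value cannot show whether blood brought the lymphocyte, neutrophil or erythroid transcripts, which stays open. WT 116 alone did not make the leukocyte calls at the preset correlation, as 7 of 7 stood without it. That test left out the erythroid and acinar lists. It also cannot give the size of that library's part. Genes called in both comparisons fell from 624 to 307 without WT 116. Other tissue rich in leukocytes, such as lymph nodes near the pancreas, a collection or sequencing batch shared by the WT livers, and the grandparents' genotype were not tested and could all remain.

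Genes called between WTMM and WTPP often lay next to each other. A family was taken as symbols with the same letters before the first digit. Symbols with only 1 letter there, such as H2 and C1q genes, had no family, so their pairs were never left out. With pairs of 1 gene family left out, 28 neighbouring pairs were called where 23.6 were expected (one-sided permutation p = 0.205), so shared reads or shared regulation within families may account for the excess, which stood at 44 pairs with families kept (permutation p = 2e-04). Within 2 Mb of genes at least 8-fold apart, 8.43% of genes were called against 3.8% elsewhere (odds ratio 2.33, Fisher exact p = 2.97e-06; 2.26 without chromosome 17), which stretches of chromosome inherited differently by the lineages could also give. Within 5 Mb of Khdc3, 3 of 50 genes were called, 6% against 4.16% elsewhere (Fisher exact p = 0.465), too few genes to exclude an excess there. Sequence variants were not analysed here, so neither explanation can be excluded.

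Clock genes set WTPP 2 and 3 apart from WTPP 6 and 7. Deviations of Arntl and Dbp from their group means had a Pearson r of -0.888 over 12 libraries, but these genes were chosen because they set WTPP apart, so the value restates the pattern and leaves collection at different clock phases open. With a clock score as a covariate, 100% of the calls of WTPP against WT kept their sign and an unadjusted p under 0.05. The score ran from -4.96 to 1.297 in WTPP, on both sides of the WT range of -3.467 to -2.465. Genes that follow it were spread within WTPP and hard to call, so this test cannot decide whether clock phase made the calls. With WTPP 2 and 3 left out, 64.2% of the calls were made again in the same direction. In WTMM the clock score ran from -4.529 to -3.555, below every WT library. Collection at different clock phases therefore stays open for WTMM against WT as well. Times of collection are not given in the sources used here, and no biological explanation was tested.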

How the results depend on the processing

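Voom, the clock covariate and leaving out WTPP 2 and 3 together were chosen after the data were seen; edgeR and DESeq2 were not run. Named genes in this section are those of the rule that were kept for the text, not all that met it. No call of a named gene turned its direction. Of 162 calls of named genes, 138 stood without WT 116, 135 without WTPP 2 and 3, 146 without the trend and 150 with voom, and all stood with a pseudocount of 0.5. Of 46 calls of lists, 40 stood without WT 116, 39 without WTPP 7, 42 with quantile normalization and 45 with voom. Depth limits genes near 10 normalized counts, and folds from 0 reads are lower bounds.

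Array weights raised the calls of WTMM against WT from 1502 to 2655 and the shared calls from 624 to 1065. A log2 fold change of at least 1 left 451, 368 and 199 calls of 1502, 1479 and 603, and 161 shared, by construction. With only the 2 groups compared, WTPP against WT had 858 calls and WTMM against WT 1620. Over single left-out libraries, calls ran from 822 (WTMM 7) to 1795 (WT 117) in WTMM against WT, 742 (WT 116) to 1997 (WT 117) in WTPP against WT, 266 (WTMM 9) to 824 (WT 117) in WTMM against WTPP, and 307 (WT 116) to 946 (WT 117) in both. Camera with an estimated correlation called 0, 0 and 0 lists of 16, 15 and 15, and fry called 4 in WTPP against WT and 5 in WTMM against WTPP. Apart from the fold limit, the cause was not tested.

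WTMM and WTPP share only mouse numbers 6 and 7, whose libraries correlated at -0.153 and -0.066, so they were not treated as a pairing. With the replicate block, 32 genes were called between WTMM and WTPP. In that fit WTMM 8, WTMM 9, WTPP 2 and WTPP 3 share no number and are fitted exactly. The contrast then rests on numbers 6 and 7 alone, so fewer calls follow from the design. Of 34 calls of named genes 9 stood, without those of Hsd3b5, Sytl5, Cyp2c55 and Rps2 (adjusted p = 0.106, 0.143, 0.058 and 0.0555). Of 15 calls of lists 10 stood, and 7 lists not called without the block were called with it. In all, 3 lists turned direction. Cell proliferation turned to -0.1331 and lost its call (camera adjusted p = 0.586). The circadian clock turned to -0.18 and Kupffer cells to -0.2249, both called only with the block.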

Other observations

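Several lists did not pass in any comparison. Of 22 imprinted genes, 0 rose and 0 fell in WTMM against WT (camera adjusted p = 0.805), and 0 rose and 1 fell in WTPP (0.866). Of 24 genes of DNA methylation and chromatin, 2 rose and 1 fell in WTMM (0.882), and 0 rose and 1 fell in WTPP (0.879). The 13 genes encoded by mitochondrial DNA had 0 calls in both (0.882 and 0.64), as did 29 nuclear oxidative phosphorylation genes (0.0541 and 0.0512). Pericentral genes had 0 calls of 18 against WT in both groups (0.761 and 0.366), and of 15 periportal genes 1 rose and 1 fell in WTMM (0.805) and 2 rose in WTPP (0.179).

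Stretches of 2 Mb held more calls than the rest of the genome in a few places. On chromosome 17 from 34 Mb, which holds class II genes, 25 of 94 tested genes were called in WTMM against WT (adjusted p = 0.00429) and 26 in WTPP against WT (adjusted p = 0.00191). On chromosome 4 from 60 Mb, where the Mup genes lie, 14 of 33 were called in WTMM against WT (adjusted p = 0.00232) and 12 between the lineages (adjusted p = 4.69e-06). Neighbouring called pairs against WT with gene families left out numbered 183 in WTMM, with 147 expected (permutation p = 4e-04), and 176 in WTPP, with 142 expected (permutation p = 0.0018). Neighbouring H2 and C1q genes were not left out as families there, so gene families may still add to these excesses.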
